A study of Mus musculus with 14 samples.

How the data were processed

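Single-cell RNA of myeloid cells from mouse brain, choroid plexus and subdural meninges was measured with droplet kits in 14 libraries, 1 per group. Libraries pooled cells of 4 mice each for the microglia and CD45hi sorts, 8 for the infected choroid plexus, 3 for day 0, 2 to 3 for each later brain library, 6 for the controls and 8 for the cured mice, per the labels. Version 2 of the 3' kit was used for the brains and for the infected and naive choroid plexus. Version 3.1, with actinomycin D during dissociation to limit stress transcription, was used for the cured and control border tissues, so values are not compared across these 2 sets. Per the submitters' processing notes, to which the processing before deposit is credited, reads were aligned to mm10 and counted with Cell Ranger, whose version is not given in the sources used here.

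The deposited matrices hold raw UMI counts per gene and droplet, per the file headers, and those of the 4 cured and control border libraries hold counts of 174 antibody-derived tags as well. Annotation tables by the authors give the barcode, library name, cluster number and class name of each cell they kept, and for 3 sets of libraries whole-number counts of the YFP transcript, per the file headers. How the authors filtered cells, clustered them and removed doublets is not given in the sources used here. Cell sets were taken as the authors' tables list them, and no further doublet caller or cell filter was applied. Each annotated barcode was matched to its matrix, and annotated cells held at least 1240 UMIs with 1.23% to 3.65% of a library's UMIs from mitochondrial genes. The 98 cells listed in both annotation tables of the treated brains were used in neither. The CD45hi matrix holds 2691 droplets and is filtered, whereas the other 12 matrices are raw. The day 0 matrix was not analysed here, and day 0 enters through the authors' classes alone. The authors' tables name the last brain library by week 9 where its label says 8 weeks, and 8 weeks is used here. The naive choroid plexus library is earlier published work that the submitters deposited again, and its number of mice is not given in the sources used here.

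With 1 library per group no spread between samples can be estimated, so no test was made and cells were not treated as replicates. For each comparison the UMIs of the chosen classes were summed per library and scaled to the sum of all genes (CPM). Each CPM value has an exact Poisson 95% interval and each fold an exact conditional (Clopper-Pearson) 95% interval, which cover counting error only. A fold against 0 UMIs is a lower bound computed with 3 counts over the library's summed cells. A list's value is the median log2 fold of its members with at least 20 UMIs over both libraries, with a 95% range from 1000 Poisson redraws and its rank among 10000 random lists of the same size drawn from 30 bins of expression (seed 20240). Shares of annotated cells have exact Clopper-Pearson 95% intervals. Where the median of all genes lay away from 0, some list medians are also given relative to it. These steps were tested on simulated data for each of the 8 comparisons set in advance. Both simulated libraries were Poisson draws from a shared profile, without spread between cells, mice or libraries. Coverage near 95% was thus built in, and the simulation checks the computation only. Among 200 planted genes of 11348 in the cured choroid plexus comparison, the true fold lay within the interval in 94% of cases, and it did in 97.5% of 199 among 11048 in the subdural one. A planted list at log2 1 came out at 0.94 in the infected choroid plexus (12545 genes) and 1.01 at 7 days (11820 genes). An unchanged list ranked at percentile 98.0 for the CD45hi comparison (11180 genes) and 2.75 at 7 days, so ranks short of the extremes carry little weight.

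The 18 gene lists, the markers of 21 cell classes, 8 comparisons, 51 alternatives and the rule for named genes were set before the data were examined. The rule takes genes with at least 50 CPM in the higher library and 20 UMIs over both, without mitochondrial, ribosomal protein, sex-linked, haemoglobin, receptor segment and unnamed genes. Of these it takes the 10 highest and 10 lowest by the ratio of CPM after addition of 10, then the 2 highest and 2 lowest members of each list described and the most abundant members of the leading lists. The lists are homeostatic microglia, disease-associated microglia, type I interferon response, interferon-gamma response and GTPases, MHC class I, MHC class II, chemokines, cytokines and inflammatory mediators, complement, scavenger and Fc receptors, alternative activation, border-associated macrophage, monocyte, glycolysis, lysosome, lipid handling, cell cycle, and immediate early and dissociation response. Some genes stand in more than 1 list. Some genes that the rule takes are not reported here. P2ry12 at 7 and 9 days is given because the rule names it at 3 days.

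Classes were compared where no cluster had 2 or more markers of another class among its 10 leading genes and more of them than of its own. The exceptions are epi BAM and the naive class ni CP epi, which hold 5 microglia markers each and are compared under those names in 2 added comparisons. This number and the removal of MF8 and of proliferating cells from the macrophage pools were set after the data were seen. The pools of the CD45hi comparison and of both choroid plexus comparisons are second versions, made after list medians of the first had been seen. The first pools and all macrophage classes are among the alternatives. Infected choroid plexus macrophages were MF2, MF3, MF4, MF5 and MF7, with MF1 and MF6 (monocyte markers), MF8 and MF-EP (epithelial transcripts) left out, and naive ones the stromal class. Those left out held 16.8% (MF1 and MF6), 6.21% (MF8) and 0.914% (MF-EP) of infected cells, and ni CP epi 3.599% of naive cells. Cured and control choroid plexus macrophages were MF 1 to 8 and MF 10, with MF 9 (monocyte markers) and epi BAM left out. The classes left out held 1.01% (MF 9), 10.99% (epi BAM) and 2.24% (proliferating) of control cells and 8.23%, 6.53% and 4.29% of cured cells. In the treated brains NC-MF (markers of non-classical monocytes) was kept apart from the macrophages, a choice made after their shares had been seen, and with it they held 39.4% on day 0. The 6 comparisons of MF8, of 8-week against naive microglia, of brain MF 2, of MF 1 to 4, of epi BAM and of subdural microglia were added after the data were seen. So was the choice of the interferon-gamma list and the list of cell identity as the leading results of each comparison.

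Fixed in advance as other ways to compute each value were median-of-ratios scaling, totals without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, cells thinned to 2000 UMIs with shallower cells left out, members with at least 1 UMI, all annotated cells, cells with at least 2 UMIs over class markers and none over T, B and neutrophil markers, and subtraction of free RNA. Free RNA was estimated from droplets with 1 to 100 UMIs and from 60 markers of absent cell types, 8 of which were left out by hand because macrophages or dendritic cells can express them. All UMIs of the markers used were read as free, and the estimate from all 60 is higher. For shares, the alternatives were cells with at least 1000 UMIs, a denominator of macrophages, monocytes, microglia and the class itself, and an own assignment by the fixed markers. The 13 alternatives added after the data were seen include all markers in the free RNA estimate, other pools, clusters of MF 1 to 4 and of subdural macrophages weighted to their control shares, sums of antibody tags, and a split of cells by Xist and Y-linked UMIs for libraries from mice of both sexes, used where both libraries kept at least 5 cells. Antibody tags were summarised as median counts per cell and named where the median was at least 10 and 2-fold above that of the other library, limits set after tag medians were seen.

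Gene positions are those of an mm10 annotation, which held 32158 of the 32285 gene IDs of the matrices. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.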

Results

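Microglia, macrophages and monocytes of the mouse brain and its borders were profiled by droplet single-cell RNA sequencing in naive mice, in mice infected with Trypanosoma brucei brucei, a protozoan parasite that reaches the brain late in the disease, and in mice cured of that infection. The 14 samples form 14 groups of 1 library each, so no spread between samples can be given and no test between groups was made. Microglia came from whole brains of naive and infected mice, sorted as CD45int CD11b+ CX3CR1hi cells, and recruited cells came from infected brains, sorted as CD45hi CD11b+ cells. Whole-brain CD45+ CD11b+ cells were taken on the day of treatment (day 0) and 3, 7 and 9 days and 8 weeks later. Border cells came from the choroid plexus, the tissue that makes the cerebrospinal fluid, of infected mice (CD45+ CD11b+) and naive mice (all CD45+ cells), and from the choroid plexus and subdural meninges of mice 9 weeks after treatment and of age-matched controls (CD45+ CD11b+). The infected choroid plexus mice, the 9-week mice and their controls carried an inducible Cx3cr1 Cre with a YFP reporter, a lineage label for cells that expressed Cx3cr1, a receptor of microglia and many border macrophages.

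Annotated cells and their summed UMIs (unique molecular identifiers, counts of captured RNA molecules) numbered 534 and 1771436 in the naive microglia sort, 1484 and 7097954 in the infected microglia sort, and 2539 and 20318455 in the CD45hi sort. The infected choroid plexus had 6781 cells with 70466818 UMIs and the naive one 3723 with 20938106. The brains had 4789 cells with 42524603 UMIs at 3 days, 4340 with 29713225 at 7 days, 2230 with 17197805 at 9 days and 4965 with 21884564 at 8 weeks. The control and cured choroid plexus had 1292 cells with 13140477 UMIs and 2005 with 26006436, and the control and cured subdural meninges had 5632 with 36609568 and 4494 with 31529597. Median UMIs per cell ran from 3199 in the naive microglia sort to 11900 in the cured choroid plexus. The brain libraries and the naive choroid plexus carried Y-linked RNA and at most 0.191 CPM of Xist, the female-specific transcript. Cells with Xist and no Y-linked UMI made up 72.5% of the infected choroid plexus, 35.8% of the control and 83.7% of the cured choroid plexus, and 34.2% and 81.0% of the control and cured subdural meninges. Values are given as CPM, the usual scaling of a gene's summed UMIs to the sum of all genes in the same cells, and each range after a value is a 95% interval for counting error only.

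The first comparison asks how infection alters microglia, the resident macrophages of brain tissue. Infected microglia held far more RNA for antigen presentation, interferon responses and chemokines than naive microglia, and less RNA of the resting microglial identity. All 8 genes of MHC class II, which presents peptides to CD4 T cells, were more than 2-fold higher, with a median log2 fold of 5.64 (4.71 to 5.74), or 5.89 relative to the median gene. All 18 homeostatic genes were lower, 14 of them by 2-fold or more, with a median of -1.57 (-1.60 to -1.50), or -1.32 relative to the median gene. The median of all genes lay at -0.25 log2.

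Ccl5, a chemokine for T cells and monocytes, stood at 4773 against 6.27 CPM, or 762-fold higher (426 to 1526), and Cxcl13, which attracts B cells, at 1178 against 0 CPM, or at least 689-fold higher. Ccl5 lies on mm10 at ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, the build used for all positions given here. The MHC class II chain H2-Aa (5304 against 38.2 CPM, 139-fold, 109 to 179) and the invariant chain Cd74 (16473 against 294 CPM, 55.9-fold, 51.3 to 61.1) stood far above the naive level. Type I interferon genes had a median of 3.75 (3.49 to 3.97), or 4.00 relative to the median gene, with 18 of 18 higher, among them the antiviral membrane protein Ifitm3 at 888 against 28.5 CPM. Interferon-gamma response genes and GTPases had a median of 3.00 (2.51 to 3.70), or 3.25 relative to the median gene, above 10000 of 10000 random lists matched for expression. That list includes the T cell chemokines Cxcl9 (456 against 0 CPM, at least 267-fold) and Cxcl10 (1275 against 101 CPM, 12.6-fold, 10.8 to 14.7). MHC class I genes, which present peptides to CD8 T cells, had a median of 1.74 (1.70 to 2.02) with 15 of 15 higher, as B2m, the class I light chain, at 12674 against 3849 CPM and the class Ib gene H2-Q7 at 969 against 39.9 CPM. Chemokines had a median of 2.41 (2.13 to 2.49) and cytokines of 2.25 (1.83 to 2.69), with the interleukin 12 chain Il12b at 116 against 0.5696 CPM, from 1 UMI in the naive library, and Il1b at 753 against 94.6 CPM.

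Fcrls, an Fc receptor-like gene of microglia, was the lowest of the homeostatic genes at 48.4 against 1842 CPM, or 38.1-fold lower (33.8 to 42.98). It lies at ENSMUSG00000015852, chromosome 3, 87250758 to 87263738. The purinergic-type receptor gene Gpr34 was also lower at 238 against 1472 CPM, or 6.19-fold lower (5.81 to 6.61), the fructose transporter gene Slc2a5 at 49.5 against 403 CPM and the protease inhibitor gene Cst3 at 9941 against 49538 CPM. Disease-associated microglia genes went both ways, 12 of 17 higher, with a median of 0.57 (0.45 to 0.84). The receptor kinase gene Axl (176 against 8.54 CPM, 20.6-fold, 12.4 to 36.9), the protease inhibitor gene Cst7 (312 against 13.1 CPM, 23.8-fold, 15.8 to 37.6) and Apoe, the lipid carrier (2701 against 672 CPM, 4.02-fold, 3.79 to 4.27), were higher, whereas the lipid sensor Trem2 was lower at 1310.4 against 2370 CPM. Immediate early genes were lower in 13 of 14, with a median of -1.56 (-1.58 to -1.53) and Fos at 3483 against 8850.2 CPM. Monocyte genes, which mark another cell type, were higher in 5 of 5 at 3.34 (2.69 to 3.99), and border-associated macrophage genes were lower in 6 of 7 at -1.35 (-1.70 to -0.42), or at -0.41 over all annotated cells. Relative to the median gene, medians stood at 0.47 for complement, 0.26 for scavenger and Fc receptors, -0.05 for alternative activation, 0.69 for glycolysis, 0.66 for lysosome, 0.37 for lipid handling and 0.65 for cell cycle genes. The naive pool was almost wholly the naive microglia cluster (527 of 532 cells), and 838 of the 1346 infected cells lay in the infected cluster Inf Mg 2. RNA shared with empty droplets was put at 9.11% of the infected and 16.6% of the naive sum, or 17.8% and 35.4% with all markers in the estimate, whose removal took the cytokine median to 1.49.

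**Figure D1:**
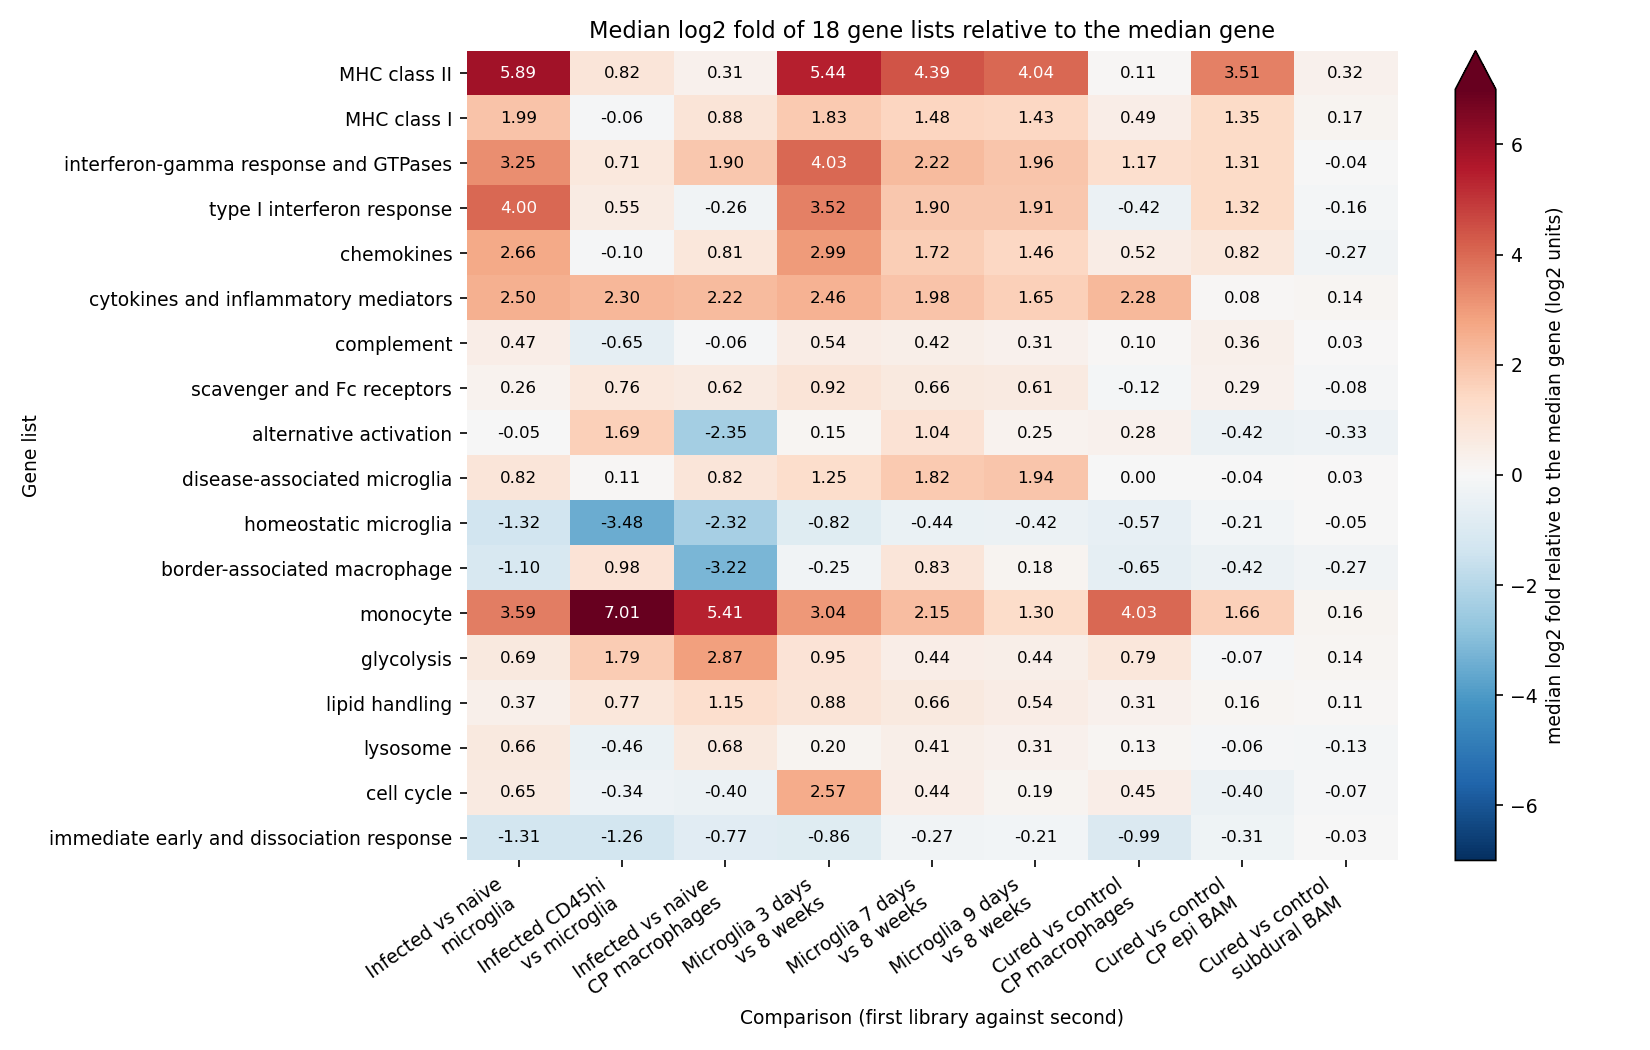
Median log2 fold of each gene list (rows) in 9 comparisons (columns), relative to the median of all genes, with red for higher in the library named first. MHC class II genes reach 5.89 in infected microglia and 3.51 in the epi BAM class of the cured choroid plexus, and monocyte genes reach 7.01 in recruited cells.

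The CD45hi cells address how recruited macrophages and monocytes differ from microglia within the same infected brains. Recruited cells carried monocyte, glycolysis and inflammatory mediator genes at higher levels and lacked most RNA of the microglial identity. All 12 monocyte genes were higher, with a median of 6.61 (6.20 to 7.29), or 7.01 relative to the median gene, and all 18 homeostatic genes were lower, with a median of -3.87 (-3.96 to -3.83), or -3.48 relative to the median gene. The median gene lay at -0.39 log2.

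The monocyte surface gene Ly6c2 stood at 2027 against 0.958 CPM, or 2116-fold higher (972 to 5766), and Hp, which encodes haptoglobin, at 943 against 0 CPM, or at least 1969.6-fold higher. Chil3, a chitinase-like protein of alternatively activated macrophages, had 2 UMIs in microglia (2338 against 0.319 CPM, 7321-fold, 2026 to 60453). Both arginine-consuming enzymes of macrophages were on the recruited side, with Arg1 at 729.5 against 0.798 CPM, or 914-fold higher (391 to 2815) and the nitric oxide synthase Nos2 at 167 against 0.958 CPM, or 175-fold higher (80.1 to 476). Saa3, an acute-phase protein, stood at 17102 against 238 CPM, or 71.8-fold higher (68.3 to 75.6) and the interleukin Il1b at 2291 against 753 CPM, and 9 of 14 cytokine and mediator genes were higher with a median of 1.91 (1.72 to 1.99), or 2.30 relative to the median gene. Glycolysis genes were higher in 12 of 13, with a median of 1.40 (1.36 to 1.46), as the enzyme genes Gapdh at 2161 against 827 CPM and Pgk1 at 449.5 against 117 CPM. Interferon-gamma response genes were close between the cell types at 0.32 (0.17 to 0.38), or 0.71 relative to the median gene, and MHC class II genes stood at 0.43 (0.31 to 0.47), or 0.82 relative to the median gene, with Cd74 at 14602 against 16473 CPM.

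On the microglial side were the purinergic receptor gene P2ry12 (16.4 against 545 CPM, 33.3-fold, 29.6 to 37.6), the membrane protein gene Tmem119 (30.3 against 965 CPM, 31.8-fold, 29.2 to 34.7) and Gpr34 (2.64 against 238 CPM, 90.2-fold, 67.9 to 122). Microglia also held more of 4 signalling genes, namely Il12b (4.196 against 116 CPM, 27.7-fold, 21.9 to 35.5), the monocyte chemokine Ccl12 (86.5 against 2165 CPM, 25.03-fold, 23.8 to 26.4), Cxcl13 (80.9 against 1178 CPM, 14.6-fold, 13.8 to 15.4) and Ccl4 at 848 against 10651 CPM. Complement genes were lower in 9 of 12 in recruited cells at -1.05 (-1.08 to -1.01), or -0.65 relative to the median gene, with the C1q chain C1qa at 3708 against 12161 CPM. Alternative activation genes had a median of 1.30 (0.81 to 1.92) over 5 measured genes and the lysosome list -0.85 (-0.91 to -0.82), or -0.46 relative to the median gene. Of the 2321 recruited cells, 688 were in MF 1, 607 in MF 3, 371 in MF 2, 324 in non-classical and 304 in classical monocytes, and the identity lists partly restate how these classes were told apart. Macrophage classes without monocytes gave a monocyte list median of 4.90. The alternative activation median moved to 6.19 in cells thinned to 2000 UMIs, 5.02 in cells that passed the marker rule and 0.60 with members of at least 1 UMI. List members were chosen anew each time, so these medians can rest on different genes.

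The choroid plexus comparison sets macrophage classes of infected mice against border-associated macrophages, the long-lived macrophages of the brain's coverings, of naive mice. Whether both pools hold cells of the same lineage is not known, so the fate of resident cells cannot be read from it. In the infected choroid plexus the macrophage classes carried more RNA of monocyte, glycolysis and interferon-gamma genes. They held less of the RNA that marks border-associated macrophages in naive mice, far less for most of its genes. All 14 border-associated macrophage genes were lower, with a median of -3.62 (-3.77 to -3.47), or -3.22 relative to the median gene, below all 10000 random lists. All 12 monocyte genes were higher, with a median of 5.01 (4.68 to 5.46), or 5.41 relative to the median gene. The median gene lay at -0.40 log2.

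The mannose receptor gene Mrc1 stood at 3.27 against 376 CPM, or 115-fold lower (95.5 to 139.5), the platelet factor gene Pf4 at 10.6 against 1664 CPM, or 156-fold lower (141 to 174), the carbonyl reductase gene Cbr2 at 1.19 against 191 CPM, or 160.1-fold lower (118 to 223) and the haemoglobin scavenger receptor gene Cd163 at 0 against 58.6 CPM, or at least 687-fold lower. Hpgd, which degrades prostaglandins, stood at 0.398 against 637 CPM, or 1599-fold lower (952 to 2926). Its position is ENSMUSG00000031613, chromosome 8, 56294585 to 56321043. Differences were smaller for the membrane protein gene Ms4a7 at 569 against 1008 CPM and the coagulation factor gene F13a1 at 61.9 against 142 CPM. Apoe, the most abundant of the named genes, stood at 16087 against 56420 CPM, or 3.51-fold lower (3.495 to 3.52), and homeostatic genes shared with microglia were lower in 15 of 16 at -2.72 (-2.75 to -2.68), led by Fcrls (1.51 against 1073 CPM, 711-fold, 544 to 950.2). Alternative activation genes were lower in 6 of 8 at -2.75 (-2.92 to -2.59).

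Saa3 was the highest gene by ratio at 23807 against 0.964 CPM, or 24703-fold higher (14446 to 46394), at ENSMUSG00000040026, chromosome 7, 46711998 to 46715700. Arg1 (732 against 0.371 CPM, 1974-fold, 846 to 6079), Nos2 (104 against 0 CPM, at least 466-fold), Ly6c2 (999.7 against 4.89 CPM, 204-fold, 161 to 264) and Ccl5 (14162 against 141 CPM, 101-fold, 96.2 to 105) were also higher. All 13 glycolysis genes were higher, with a median of 2.47 (2.40 to 2.52), or 2.87 relative to the median gene, among them the pyruvate kinase gene Pkm at 1688 against 176 CPM, or 9.57-fold higher (9.19 to 9.98), Pgk1 at 508 against 56.6 CPM and Gapdh at 2529.6 against 373 CPM. Interferon-gamma response genes were higher in 17 of 19, with a median of 1.50 (1.31 to 1.58), or 1.90 relative to the median gene, as Cxcl9 at 528 against 31.5 CPM, or 16.8-fold higher (15.2 to 18.5) and the GTPase gene Gbp2 at 432 against 22.3 CPM. Type I interferon genes were lower in 12 of 18 at -0.66 (-0.77 to -0.49), or -0.26 relative to the median gene, with Ifit3 at 16.95 against 78.8 CPM and Usp18 at 12.4 against 48.6 CPM. Cytokines and mediators had a median of 1.82 (1.75 to 2.05), lipid handling 0.76 (0.73 to 0.78), MHC class II -0.09 (-0.12 to -0.03) and MHC class I 0.48 (0.47 to 0.50). Relative to the median gene these are 2.22, 1.15, 0.31 and 0.88. Immediate early and dissociation response genes had a median of -1.17, or -0.77 relative to the median gene.

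The infected pool held 1139 cells of MF4, 1065 of MF3 and 580 of MF2, and the naive pool was the stromal macrophage class alone. The naive library is earlier published work, from another strain per the labels and with almost no Xist, and infected cells with Y-linked RNA and no Xist (312 of 3155) gave -2.80 for the border-associated and 2.07 for the interferon-gamma list. After subtraction of free RNA the monocyte median was 8.48, a size that carries little weight because the subtraction cut the naive counts further. Thinned cells gave -2.49 for the border-associated list.

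Apart from these macrophages, the choroid plexus holds a microglia-like class, which the YFP label marks strongly. A YFP count was found in 82.4% of the 421 cells of the infected class MF8, against 4.50% of the 3155 pooled macrophages, 1.27% of monocytes and 3.06% of T cells, which should lack the label. Median UMIs were 11743 in MF8, 10813 in the macrophages, 7538 in the monocytes and 6563 in the T cells, and thinning to 2000 UMIs gave 55.8%, 2.00%, 0.477% and 1.75%. MF8 was set against the naive class ni CP epi (134 cells), whose 10 leading genes hold 5 microglia markers and none of the epithelium. The pairing was added after the data were seen because Sparc and Syngr1 are among the leading genes of both.

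Infected MF8 cells carried antigen presentation and interferon genes at higher levels, as infected microglia did, with MHC class II at 2.94 (2.62 to 3.06), interferon-gamma genes at 2.92 (2.67 to 3.40), type I interferon genes at 2.24 (1.79 to 2.51) and MHC class I at 1.79 (1.64 to 1.90). Cxcl13 (3491 against 0 CPM, at least 1600.3-fold), Saa3 (4737 against 0 CPM, at least 2171-fold) and Ccl5 (8947 against 197 CPM, 45.4-fold, 40.3 to 51.3) were far higher, and H2-Aa stood at 10164 against 823 CPM. Free RNA was put at 11.8% of the MF8 and 3.42% of the naive sum, or 13.1% and 4.38% with all markers. Saa3 and Ccl5 were more abundant still in the infected macrophages of the same library, so free RNA may hold part of their counts in MF8. Homeostatic genes were lower in 17 of 18 at -1.74 (-1.86 to -1.67), with Fcrls at 5.91 against 1623 CPM, or 275-fold lower (192 to 408) and the lectin gene Siglech at 64.6 against 656 CPM. All 10 measured border-associated genes were lower at -2.09 (-2.27 to -1.78), with Pf4 at 1.97 against 144 CPM and Mrc1 at 0.788 against 45.1 CPM. The cytokine median of 1.97 was 0.92 after subtraction of free RNA estimated from all markers, 0.46 in cells that passed the marker rule and 0.045 in cells with Y-linked RNA alone, and in thinned cells alternative activation turned from -1.32 to 1.20. All annotated cells of the libraries gave 0.07 for MHC class II, 0.00022 for type I interferon, 1.77 for interferon-gamma, 0.61 for MHC class I and -3.35 for border-associated genes. The type I interferon median was 3.38 in cells that passed the marker rule.

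Whole-brain libraries after treatment show how the composition of myeloid cells differed with time from cure. Microglia made up 15.6% (14.98 to 16.3) of annotated cells on day 0 and 17.7% (16.7 to 18.9) at 3 days, then 49.2% (47.7 to 50.7) at 7 days, 58.99% (56.9 to 61.05) at 9 days and 90.4% (89.5 to 91.2) at 8 weeks. Macrophages made up 35.6% on day 0, 45.2% at 3 days, 15.4% at 7 days, 18.2% at 9 days and 2.904% at 8 weeks. They leave out class NC-MF, whose leading genes include 2 markers of non-classical monocytes and which held 3.79% on day 0. The macrophage classes changed with time, with MF 1 at 31.4% of cells on day 0 and MF 2 at 40.3% at 3 days. MF 3 held 1.23%, 2.76%, 7.65%, 8.58% and 2.80% from day 0 to 8 weeks. Classical monocytes stood at 18.4%, 23.6%, 22.9%, 12.8% and 3.73% in the same order, and non-classical monocytes at 25.8%, 12.3%, 11.2%, 9.44% and 2.96%. Proliferating cells of mixed type, kept out of these classes, were 0.751%, 0.712%, 1.19% and 0.452% of cells from day 0 to 9 days. All 5 libraries share the CD45+ CD11b+ gate and the kit. Assignment by the fixed markers alone placed 3.33%, 20.6%, 32.5% and 75.2% of cells from 3 days to 8 weeks in microglia.

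**Figure D2:**
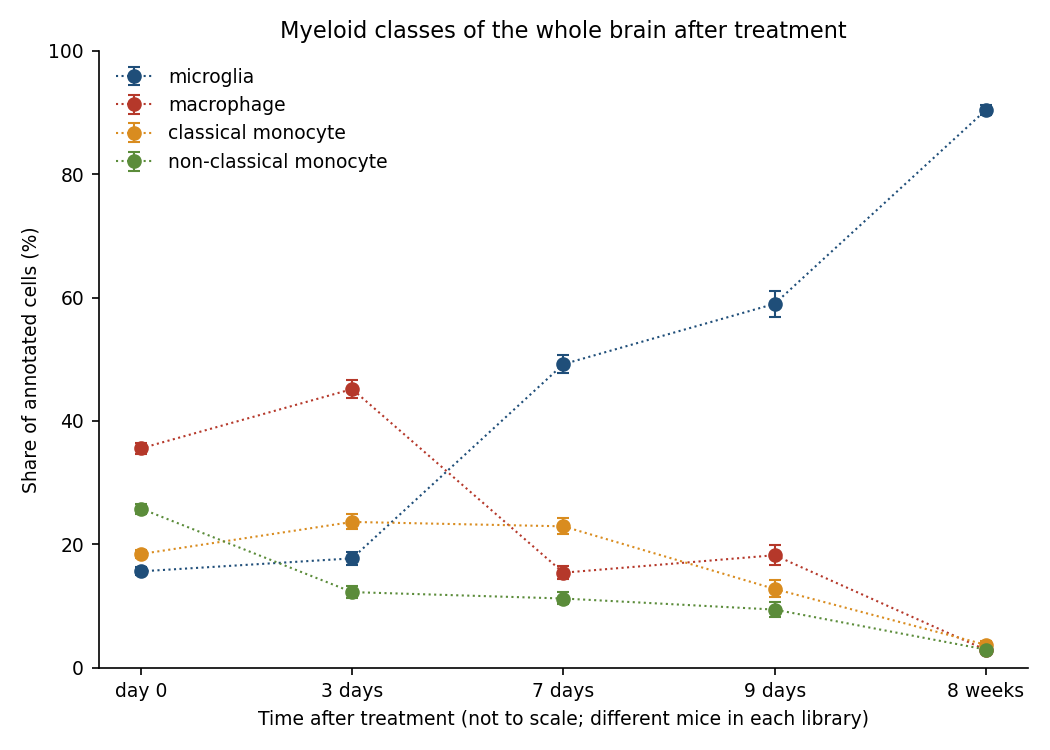
Share of annotated whole-brain cells (percent) in 4 classes on day 0 and 3, 7 and 9 days and 8 weeks after treatment, with exact 95% intervals as bars. Microglia stand at 15.6% on day 0 and 90.4% at 8 weeks.

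Microglia at 3, 7 and 9 days were each set against microglia at 8 weeks, to ask how long the infected profile lasts after treatment. At 3 days the microglia still carried the interferon and antigen presentation genes of infected microglia, and at 9 days these genes were lower than at 3 days yet far above their 8-week level. Genes of MHC class II had medians of 5.15 (5.12 to 5.17), 4.12 (3.83 to 4.45) and 3.82 (3.53 to 4.18) at 3, 7 and 9 days, with 8 of 8 higher each time. Homeostatic genes were lower in 18 of 18 each time, with medians of -1.11 (-1.14 to -1.09), -0.71 (-0.74 to -0.69) and -0.64 (-0.65 to -0.62). The median gene lay at -0.29, -0.27 and -0.22, so relative to it MHC class II stood at 5.44, 4.39 and 4.04 and the homeostatic list at -0.82, -0.44 and -0.42.

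Against 123 CPM at 8 weeks, H2-Aa stood at 6664 CPM at 3 days, 4409 at 7 days and 3274 at 9 days, which is 54.3-fold higher (52.1 to 56.7), 35.9-fold higher (34.5 to 37.5) and 26.7-fold higher (25.6 to 27.9). Cd74 stood at 24775, 19625 and 15429 CPM against 601, and Ccl5 at 3148, 1009.9 and 853 CPM against 27.4, which is 115-fold higher (105 to 126) at 3 days. Interferon-gamma response genes had medians of 3.74 (3.25 to 3.92), 1.94 (1.62 to 2.05) and 1.73 (1.62 to 1.84), or 4.03, 2.22 and 1.96 relative to the median gene. In thinned cells the 7-day median was 1.26. Their chemokine Cxcl9 was 63.6-fold higher (55.5 to 73.1) at 3 days and 15.2-fold higher (13.2 to 17.6) at 7 days. Type I interferon genes were higher in 18 of 18 each time, at 3.23, 1.63 and 1.69, and their regulator Irf7 stood at 319 against 14.1 CPM at 3 days. MHC class I genes stood at 1.54, 1.20 and 1.21, with H2-Q7 at 800.5 against 106 CPM at 9 days. Saa3 was 363-fold higher (234 to 595) at 3 days, and Cxcl13 stood at 1147, 250.5 and 216 CPM against 6.27.

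Disease-associated microglia genes had medians of 0.96 (0.78 to 1.23), 1.54 (1.03 to 1.73) and 1.72 (1.53 to 1.85), an order that did not hold in thinned cells (0.97, 1.47 and 0.99) or in cells that passed the marker rule (0.74, 0.33 and 1.07). Apoe stood at 8990.5, 9592 and 11017 CPM against 1779, Axl at 97.8 against 20.96 CPM at 7 days and 111 against 20.96 CPM at 9 days, and Spp1, which encodes osteopontin, at 45.5 against 4.95 CPM at 7 days. Among homeostatic genes, Fcrls was 23.1-fold lower (20.6 to 26.00) at 3 days, 4.06-fold lower (3.93 to 4.202) at 7 days and 4.05-fold lower (3.895 to 4.21) at 9 days, and P2ry12 was 5.29-fold, 2.26-fold and 2.07-fold lower. Gpr34 stood at 239 against 1692 CPM at 3 days. Cell cycle genes had medians of 2.29, 0.16 and -0.04, although proliferating microglia were left out, with 1.45 at 3 days in thinned and 3.65 over all annotated cells, and monocyte genes 2.75, 1.87 and 1.07. Chemokines stood at 2.70, 1.44 and 1.24, cytokines at 2.17, 1.70 and 1.43 and the complement gene C4b at 134 against 7.74 CPM at 7 days. All 3 comparisons share the 8-week library, so they are not independent of each other. Cells that passed the marker rule (23, 16 and 39 against 633) gave 0.52 for the interferon-gamma list at 9 days, 2.58 for type I interferon genes at 7 days, 0.68 and -0.023 for cytokines at 7 and 9 days and -0.04 for the cell cycle list at 3 days. Subtraction of free RNA gave 2.49 for cytokines at 9 days, and with all markers in the estimate 3.26 and 2.64 at 3 and 9 days and 4.63 for monocyte genes at 3 days.

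**Figure D3:**
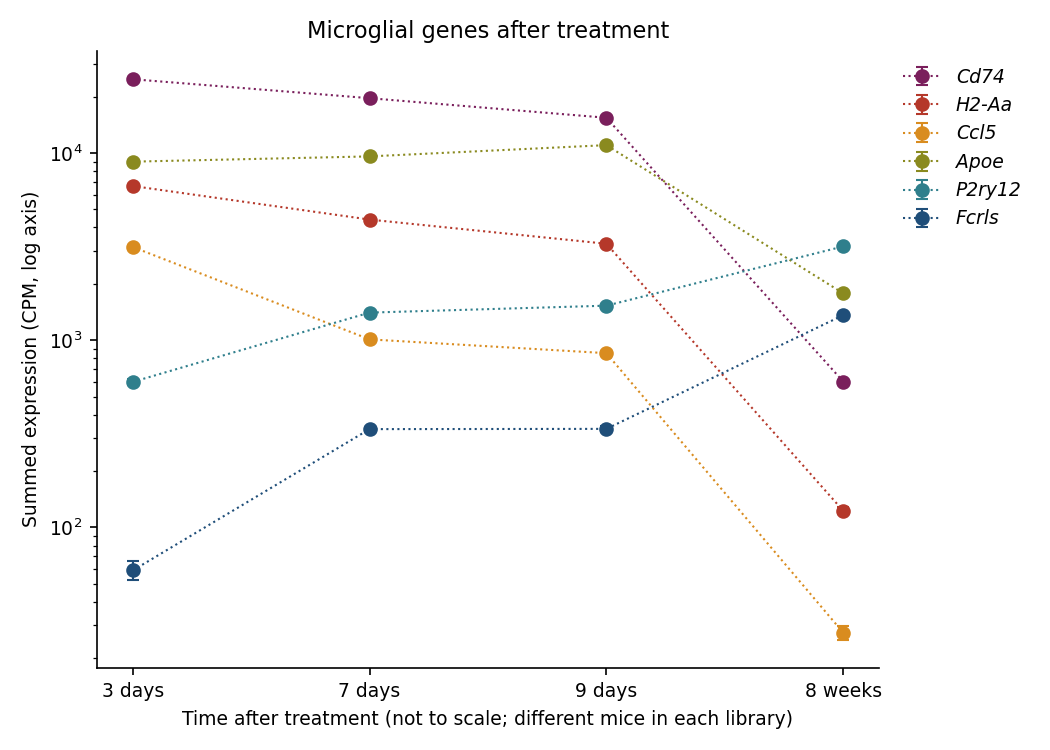
Summed expression of 6 genes in microglia (CPM on a log axis) 3, 7 and 9 days and 8 weeks after treatment, with exact Poisson 95% intervals as bars, most of them smaller than the points. H2-Aa, Cd74 and Ccl5 are lowest and P2ry12 and Fcrls highest at 8 weeks.

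Microglia 8 weeks after treatment were also set beside the naive microglia sort, a comparison added after the data were seen that joins separate experiments and gates. Differences were far smaller than those between infected and naive microglia, with monocyte, MHC and interferon genes somewhat higher at 8 weeks. MHC class II genes were higher in 8 of 8 at 1.06 (0.82 to 1.25), with H2-Ab1 (249.8 against 56.96 CPM, 4.39-fold, 3.598 to 5.402), H2-Aa (123 against 38.2 CPM, 3.21-fold, 2.52 to 4.16) and Cd74 (601 against 294 CPM, 2.04-fold, 1.87 to 2.23). MHC class I stood at 0.81 (0.64 to 0.98), type I interferon genes at 0.84 (0.59 to 1.09), interferon-gamma genes at 0.94 (0.46 to 1.11) and homeostatic genes at 0.22 (0.18 to 0.24), and Apoe at 1779 against 672 CPM. Monocyte genes, which mark another cell type, were higher in 9 of 10 at 1.33 (1.02 to 1.89), or 2.35 in cells that passed the marker rule. Free RNA was put at 4.19% of the 8-week and 16.6% of the naive sum, and its subtraction took the MHC class II median to 0.68, beside 0.69 in cells that passed the marker rule. With all markers in the estimate these shares were 6.45% and 35.4%, the median was 0.27 and H2-Aa turned to -4.48. The naive share rests on 444 UMIs of the markers. The H2-Aa value arose because the subtraction removed nearly all 8-week counts of this gene, so its size carries little weight.

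Brain macrophages of class MF 2, the class that held 1924 cells at 3 days and 210 at 9 days, were compared between these days, also after the data were seen. Chil3 was 10.9-fold lower (9.37 to 12.6) at 9 days, from 72.6 against 788 CPM, Saa3 was 2.67-fold lower (2.59 to 2.76), and Arg1 was 1.898-fold lower (1.67 to 2.16). The lectin gene Mgl2 was 8.45-fold higher (6.07 to 11.8). Alternative activation genes had a median of -0.92 (-1.11 to -0.75), which thinning moved to -0.50 and subtraction of free RNA to -0.50, and type I interferon genes were higher in 18 of 18 at 0.45 (0.38 to 0.48).

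The 9-week libraries ask whether the brain's borders return to their former state after cure. In the cured choroid plexus, macrophages differed in kind from the controls, with interferon-gamma, monocyte and cytokine genes at higher levels and border-associated macrophage genes at lower levels. Classes MF 1 to 4 held 73.8% (71.4 to 76.2) of control and 19.6% (17.9 to 21.4) of cured cells, and classes MF 5 to 8 with MF 10 held 4.799% (3.699 to 6.11) and 33.02% (30.96 to 35.1). Class names go with cluster numbers in the authors' tables, so these sizes can restate differences in the genes below. Dendritic cells of type cDC2, which prime T cells, made up 4.95% (3.84 to 6.28) and 17.1% (15.5 to 18.8), and migratory dendritic cells 0.155% and 6.03%. B or plasma cells stood at 0.0774% and 2.04%. T cells stood at 1.496% in the cured library and 0 of 1292 cells in the control, where a floor of 3 cells, not an exact interval, would be 0.232%.

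Over the pooled macrophages, interferon-gamma response genes were higher in 19 of 19, with a median of 1.11 (1.02 to 1.22), above all 10000 random lists. Cxcl9 stood at 2171 against 149.5 CPM, or 14.5-fold higher (13.7 to 15.4), Cxcl10 at 465 against 60.3 CPM and B2m at 4652 against 3609 CPM. The B cell chemokine Cxcl13, at ENSMUSG00000023078, chromosome 5, 95956951 to 95961068, stood at 2955 against 165 CPM, or 17.95-fold higher (17.04 to 18.9), Ccl8, a chemokine for monocytes and T cells, at 4065 against 139.7 CPM, or 29.1-fold higher (27.5 to 30.8), and the complement gene C3 at 398 against 27.1 CPM. The fatty acid binding protein gene Fabp5 (625 against 5.78 CPM, 108-fold, 82.2 to 146) and the calcium-binding protein gene S100a4 (433 against 4.19 CPM, 103-fold, 74.8 to 147) were also far higher. Ctsk and Acp5, enzymes of bone-resorbing cells, stood at 137 against 0.227 CPM and 321 against 9.51 CPM and were the leading genes of MF 10, a class of 9 cells. Monocyte genes were higher in 8 of 10 at 3.97 (3.80 to 4.82), with Ly6c2 at 41.8 against 0.3398 CPM, from 3 UMIs in controls. Cytokines and mediators were higher in 9 of 12 at 2.22 (1.80 to 2.91), or at 1.04 in cells with Y-linked RNA alone, although Il1b was lower at 277 against 624 CPM. Chemokines as a list were higher in 11 of 16 at 0.46 (0.38 to 0.74).

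Border-associated macrophage genes were lower in 10 of 13, with a median of -0.71 (-0.80 to -0.58), below all 10000 random lists. F13a1 stood at 8.71 against 56.3 CPM, or 6.47-fold lower (5.24 to 8.04), Cbr2 at 3.71 against 29.7 CPM, or 8.004-fold lower (5.83 to 11.2), Mrc1 at 279 against 518 CPM, or 1.86-fold lower (1.78 to 1.95) and Pf4 at 409 against 776 CPM, or 1.89-fold lower (1.83 to 1.97). Apoe stood at 38257 against 58331 CPM. Type I interferon genes were lower in 15 of 18 at -0.48 (-0.60 to -0.42), and glycolysis genes were higher in 12 of 13 at 0.73 (0.59 to 0.79), or at 0.42 in thinned cells. Immediate early genes were lower in 14 of 14 at -1.05 (-1.20 to -0.85), but at -0.52 over all macrophage classes and -0.20 over all annotated cells. MHC class I genes stood at 0.43 (0.36 to 0.57) and MHC class II genes at 0.05 (0.04 to 0.06). Of the pooled cells, 954 of 1016 control cells lay in MF 1 to 4 and 662 of 1055 cured cells in MF 5 to 8 and MF 10, so the pools differ in cluster makeup. The monocyte median was 1.91 over all macrophage classes, 2.53 in the first pool and 0.90 over all annotated cells. The border-associated median was -0.33 in thinned cells, -0.38 in cells with Xist alone, -1.28 in cells with Y-linked RNA alone and -1.13 over all annotated cells.

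Within MF 1 to 4 alone, a comparison added after the data were seen, the cured cells (393 against 954) still had fewer border-associated transcripts, with 12 of 13 genes lower at -1.14 (-1.24 to -0.98), or -1.01 relative to the median gene, and the median gene at -0.13. MF 4, whose 10 leading genes include 4 border-associated markers, held 367 of these control and 68 of these cured cells, and MF 3 held 369 and 111. With the cured clusters weighted to their control shares the median was -0.71, with Mrc1 at log2 -0.48 and Pf4 at -0.71. Part of the difference thus goes with the mix of clusters. Mrc1 was 2.11-fold lower (1.96 to 2.28), and Pf4 was 2.27-fold lower (2.12 to 2.42). Cxcl9 was 6.05-fold higher (5.33 to 6.87), Ccl8 3.73-fold higher (3.39 to 4.104), and Cxcl13 3.12-fold higher (2.897 to 3.36). Interferon-gamma genes as a whole stood at -0.06 (-0.17 to 0.11), or 0.35 with weighted clusters. Type I interferon genes were lower in 17 of 18 at -0.86 (-0.97 to -0.72), as Irf7 at 30.6 against 80.98 CPM, but at -0.43 with weighted clusters, -0.37 in cells that passed the marker rule and -0.26 over all annotated cells. The border-associated median was -0.43 in cells with Xist alone and -0.67 in cells with Y-linked RNA alone.

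The YFP label was found in fewer cured than control macrophages of MF 1 to 4, with 26.5% (22.2 to 31.1) against 42.98% (39.8 to 46.2) of cells holding a YFP count. Classes MF 5 to 8 with MF 10 stood at 31.3% against 32.3% and epi BAM at 67.9% against 83.1%. The cDC2 cells, which should lack the label, stood at 2.62% against 1.56%, at median UMIs of 15037 and 16433, and MF 1 to 4 had 7807 and 7934. Cells thinned to 2000 UMIs gave 16.2% against 33.4% in MF 1 to 4 and 37.7% against 56.4% in epi BAM. Within MF 1 to 4, class MF 4 held 367 of the 954 control and 68 of the 393 cured cells. The label shares were not weighted to this makeup, so the mix of clusters stays open for them.

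**Figure D4:**
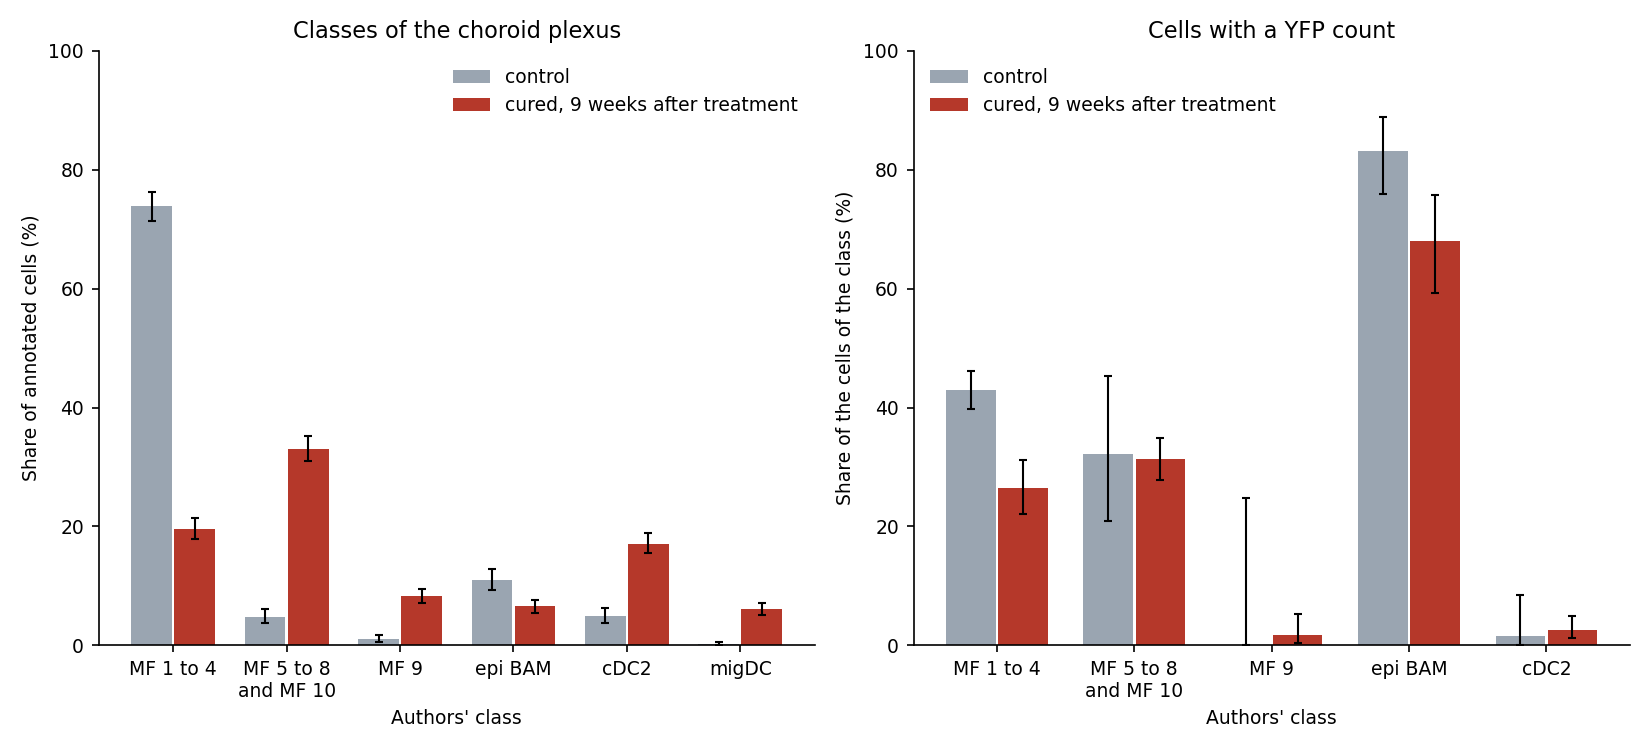
Share of annotated choroid plexus cells per class (left, percent) and share of the cells of each class with a YFP count (right, percent) in the control and cured libraries, with exact 95% intervals as bars. MF 1 to 4 hold 73.8% of control and 19.6% of cured cells, and 42.98% and 26.5% of them carry YFP.

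Epi BAM cells, which resemble microglia and made up 10.99% of control and 6.53% of cured cells, were compared after the data were seen. The cured epi BAM cells carried MHC class II genes at far higher levels than control cells while most of their microglia-like genes stayed close. MHC class II genes were higher in 8 of 8 at 3.46 (3.09 to 3.57), with H2-Aa (2120 against 136 CPM, 15.6-fold, 13.8 to 17.6), H2-Ab1 (1732 against 154 CPM, 11.2-fold, 9.999 to 12.6), H2-Eb1 (861 against 53.3 CPM, 16.1-fold, 13.3 to 19.7) and Cd74 (5524 against 483 CPM, 11.4-fold, 10.7 to 12.2). Cxcl13 was the highest gene by ratio (2464 against 24.3 CPM, 101-fold, 77.05 to 136), and Cxcl9 (108 against 2.81 CPM, 38.5-fold, 17.3 to 107) and C4b (95.1 against 2.34 CPM, 40.7-fold, 16.99 to 127) were also higher. Interferon-gamma genes stood at 1.26 (1.07 to 1.87), MHC class I genes at 1.30 (1.02 to 1.33) and type I interferon genes at 1.26 (0.71 to 1.36), with H2-Q7 at 229.8 against 34.6 CPM. Homeostatic genes were lower in 15 of 18 at -0.27 (-0.33 to -0.20), with Fcrls at 617 against 1510.5 CPM and Tmem119 at 483 against 407 CPM, and Spp1 stood at 111 against 419 CPM. Monocyte genes, which mark another cell type, were higher in 4 of 4 at 1.60 (1.008 to 2.19), or 2.56 after subtraction of free RNA estimated from all markers. Cells with Y-linked RNA alone (6 against 80) gave 0.68 for MHC class II, 0.83 for interferon-gamma, 0.69 for MHC class I and 0.55 for type I interferon genes. The type I median was 0.61 in cells with Xist alone, and the interferon-gamma median 0.81 in thinned cells. All annotated cells gave 0.16 for MHC class II, 0.65 for MHC class I and -0.26 for type I interferon genes.

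**Figure D5:**
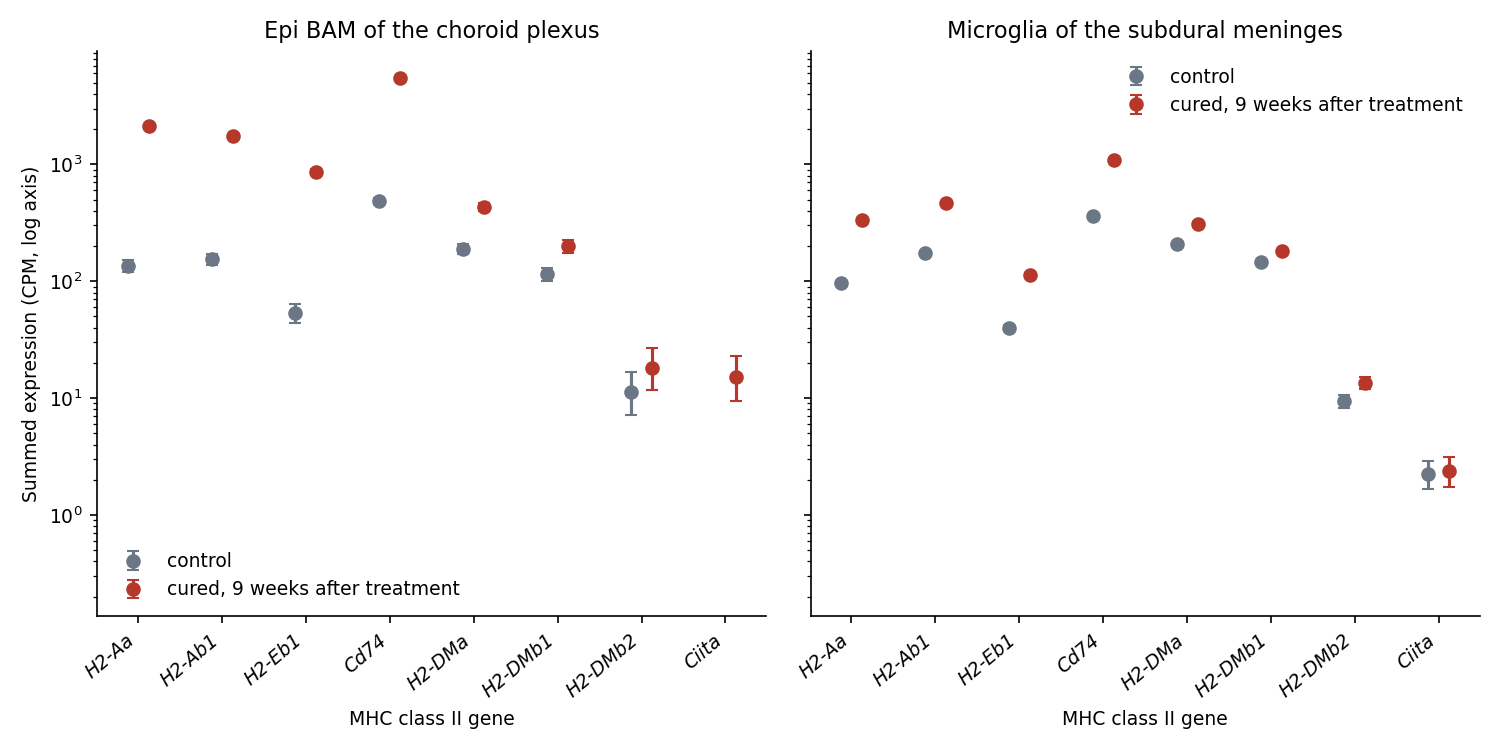
Summed expression of the 8 MHC class II list genes (CPM on a log axis) in control and cured epi BAM of the choroid plexus and in control and cured microglia of the subdural meninges, with exact Poisson 95% intervals as bars. H2-Aa stands at 2120 against 136 CPM in epi BAM and 331 against 96.00 CPM in subdural microglia, and Ciita has no UMI in control epi BAM.

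By the pooled border-associated and interferon-gamma medians, macrophages of the subdural meninges were nearer to their controls than those of the choroid plexus. For border-associated genes this order turned in cells with Xist alone, and MHC class II genes went the other way. For interferon-gamma genes the order depends on the clusters pooled. Within MF 1 to 4 of the choroid plexus their median was -0.06 (-0.17 to 0.11), or 0.35 with weighted clusters. Subdural border-associated macrophages (BAM 1 and BAM 2, 881 cured and 836 control cells) had lower levels of all 15 border-associated genes, none by 2-fold, with a median of -0.33 (-0.36 to -0.27), below all 10000 random lists. That median was -0.55 in cells with Xist alone, -0.18 in cells that passed the marker rule and -0.046 over all annotated cells. BAM 2, with 5 border-associated markers among its 10 leading genes, held 515 of the 836 control and 486 of the 881 cured cells. With the cured clusters weighted to their control shares the median was -0.19. Mrc1 stood at 1865 against 2428 CPM, or 1.302-fold lower (1.27 to 1.33), Pf4 at 1906 against 2400.4 CPM, or 1.26-fold lower (1.23 to 1.29), the folate receptor gene Folr2 at 202 against 371 CPM, or 1.84-fold lower (1.72 to 1.97) and the ficolin gene Fcna at 16.5 against 54.6 CPM, or 3.31-fold lower (2.66 to 4.13). MHC class II genes were higher in 8 of 8 at 0.26 (0.25 to 0.30), or 0.15 with weighted clusters, with H2-Aa at 9888 against 7755 CPM and Cd74 at 22208 against 18679 CPM. Cxcl2, a neutrophil chemokine, stood at 0.885 against 16.01 CPM, or 18.1-fold lower (8.01 to 50.5). In cells with Y-linked RNA alone (94 of the 881 cured cells) its log2 fold was 1.32, which rests on very few cured UMIs and carries little weight. Interferon-gamma genes were lower in 15 of 18 at -0.11 (-0.24 to -0.06), but within sexes they stood at -0.01 in cells with Xist alone and 0.43 in cells with Y-linked RNA alone. Likewise Cxcl9 was lower in the pool at 379 against 578 CPM and higher within both, at log2 1.15 and 1.23, and Ccl8 stood at 1642 against 2660.4 CPM in the pool and log2 0.70 and -0.27 within. Border-associated macrophages made up 14.8% (13.9 to 15.8) of control and 19.6% (18.5 to 20.8) of cured cells, microglia 75.8% and 69.5%, cDC2 cells 2.82% and 3.16% and neutrophils 0.604% and 1.65%. A YFP count was found in 20.8% of control and 22.5% of cured border-associated macrophages, and in 3.77% and 3.52% of cDC2 cells, at median UMIs of 6544, 7007, 13486 and 13056, and thinning to 2000 UMIs gave 12.6%, 14.4%, 1.89% and 0.704%.

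Subdural microglia, compared after the data were seen, again showed MHC class II genes at higher levels in cured mice, 8 of 8 genes at 1.00 (0.97 to 1.11). H2-Aa (331 against 96.00 CPM, 3.45-fold, 3.29 to 3.61), H2-Ab1 at 465 against 174 CPM and Cd74 (1091 against 359 CPM, 3.04-fold, 2.97 to 3.12) were higher, as were Cxcl9 (75.96 against 14.7 CPM, 5.18-fold, 4.61 to 5.82), Axl (18.1 against 6.24 CPM, 2.904-fold, 2.396 to 3.53) and Apoe (2686 against 1181 CPM, 2.28-fold, 2.24 to 2.31). Cxcl10 was lower at 3.53 against 24.1 CPM, or 6.83-fold lower (5.31 to 8.89), and homeostatic genes stood at -0.10 (-0.12 to -0.09), with Fcrls at 1824 against 2266 CPM. Cluster Mg 3 held 1101 of 3125 cured and 322 of 4269 control cells. The MHC class II median was 1.69 after subtraction of free RNA, 4.24 with all markers in that estimate, 0.46 over all annotated cells, 1.78 in cells with Xist alone and 0.69 in cells with Y-linked RNA alone. Free RNA from all markers was put at 7.09% of the cured and 14.3% of the control sum. The size of 4.24 carries little weight, since the subtraction cut the low control counts further.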

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

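The tests of YFP-positive cells and of epi BAM cells with Xist alone, the comparisons of epi BAM and of 8-week with naive microglia, and the summary of antibody tags by medians were chosen only after the results were seen, and the other tests were set down before their values. No test between groups stands behind any value here, since each group is 1 library.

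Antibody tags, which no comparison of RNA used, carried signal above the control level in the cured choroid plexus. In pooled macrophages the median counts per cell were 13 against 3 for CD274 (the inhibitory ligand PD-L1), 20 against 4 for CD38 and 16 against 2 for Ly6A-Ly6E (Sca-1). Within MF 1 to 4 these medians were 3 against 3, 6 against 3.5 and 2 against 2, and 954 of 1016 control but only 393 of 1055 cured cells of the pool lay in those classes. In epi BAM the IA-IE tag, which binds MHC class II protein, had a median of 41 against 2. Means per cell, which single droplets weigh on, were 30.8 against 5.17 for CD274, 46.8 against 18.4 for CD38, 65.9 against 23.5 for Ly6A-Ly6E and 189 against 27.9 for IA-IE. The 9 isotype control tags had medians of at most 2, and total tags per cell were 2705 against 2691.5 in macrophages and 494 against 627.5 in epi BAM. In the other direction, under the same limits, 1 tag in macrophages and 3 tags in epi BAM were at least 2-fold higher in controls. These were CD14 in macrophages (55 against 121), and CD14 (6 against 12), CD172a (12 against 24) and CD29 (11 against 24) in epi BAM.

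MHC class II genes were higher in cured than in control epi BAM, with a list median of 3.46. Free RNA is argued against by a median of 4.04 (3.80 to 4.27) after its subtraction, or 6.03 with all markers in the estimate. The size of 6.03 carries little weight, since the subtraction cut the low control counts further. Admixture of cDC2 cells is argued against as well. Conventional dendritic cell markers imply -0.00046 (-0.0657 to 0.0714) of the 13.8% of cDC2 RNA that the MHC class II genes would need. Most of these counts were Itgax (21.6 against 31.3 CPM) and Wdfy4 (18.7 against 15.4 CPM), which control epi BAM held too. Cd209a stood at 3.60 against 0.468 CPM beside 644 CPM in cDC2 cells, and Clec10a at 2.16 against 0 CPM beside 390 CPM. Migratory dendritic cells were not tested and stay open. The sex of the mice is argued against as the whole of the difference by 3.68 (3.39 to 3.94) in cells with Xist alone (113 against 41), and stays open for cells with Y-linked RNA alone, which gave 0.68 (0.31 to 1.14) from 6 cured cells. Other macrophages mixed into the class were not tested and stay open. In the cured pooled macrophages the IA-IE tag had a median of 1649. Monocyte genes stood at 1.60 in epi BAM. A lasting effect of the cured infection may remain as a hypothesis, untested beyond these 2 libraries.

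Border-associated macrophage genes were lower in infected than in naive choroid plexus macrophages, with a list median of -3.62. Free RNA is argued against by -3.76 (-3.91 to -3.61) after its subtraction. That labelled resident cells kept these genes among unlabelled recruits stays open, although the 142 cells with a YFP count gave -3.13 (-3.85 to -2.89) and the 74 with at least 2 counts gave -3.54 (-3.90 to -2.80). Such counts may be background in most of these cells. YFP counts were found in 4.50% of the pooled macrophages and 3.06% of T cells, or 2.00% and 1.75% after thinning to 2000 UMIs. Whether the infected pool is mainly resident or recruited cells thus stays open. Strain, sort gate and experiment differ between these libraries along with infection, so they stay open together with infection itself, and none was tested. Sex makeup differs too, with Xist alone in 72.5% of infected and 0.0269% of naive cells. Depth also differs, with median UMIs of 10813 and 4869. In cells with Y-linked RNA alone and in thinned cells the list was still lower, but by less.

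MHC class II genes were higher in microglia at 8 weeks after treatment than in naive microglia, with a list median of 1.06. Free RNA stays open, since its subtraction gave 0.68 (0.46 to 0.89) and free RNA differed in share, at 4.19% at 8 weeks and 16.6% in the naive sort, or 6.45% and 35.4% from all markers. A small minority of strongly positive cells also stays open, since the median without the 5% of cells highest in these genes was 0.87 (0.76 to 1.33). Gate and experiment differ between these libraries and cannot be separated from time after cure, which was not tested.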

How the results depend on the processing

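The alternatives on pools, sexes, tag sums and a free RNA estimate from every marker, and all alternatives of the 6 added comparisons, were chosen after the data were seen, and the others were planned. Each library is the only one of its group, so these alternatives test the processing and say nothing of the spread between mice. No paired analysis was possible because each group has 1 library and no result comes from a test.

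Over all reported values, 2245 alternatives stayed within the counting range of the value, 1806 moved beyond it and 7 turned a difference of at least 1 on the log2 scale. Of the log2 values that moved, 826 lay further from 0, 817 nearer to 0 and 151 across it, from reported values under 1 in size. The interferon-gamma list in infected against naive microglia stayed within its range under every alternative run. In the 8 comparisons set in advance, identity lists kept their direction under every alternative run, and interferon-gamma lists did so with the exception of subdural macrophages. Weighting of clusters was not run on the pooled choroid plexus macrophages of cured mice. The added comparison of MF 1 to 4 alone gave -0.06 (-0.17 to 0.11) for their interferon-gamma list, so that direction depends on the clusters pooled.

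Identity medians are given for homeostatic genes in microglia and recruited cells and for border-associated genes in border macrophages. Median-of-ratios scaling, which sets the median gene near 0, gave identity medians of -1.32 in infected microglia, -3.48 in recruited cells, -3.22 in infected choroid plexus macrophages and -0.82, -0.44 and -0.42 in microglia at 3, 7 and 9 days. It gave interferon-gamma medians of 0.71 in recruited cells, 1.90 in infected choroid plexus macrophages, 4.03, 2.22 and 1.96 at 3, 7 and 9 days and -0.044 in subdural macrophages. Totals without mitochondrial and ribosomal protein genes gave homeostatic medians of -1.39 in infected microglia and -1.004, -0.60 and -0.53 at 3, 7 and 9 days, and an interferon-gamma median of 2.06 at 7 days. The mean of per-cell CPM gave -1.46 in infected microglia, -4.04 in recruited cells, -3.28 in infected choroid plexus macrophages, -0.996, -0.64 and -0.56 at 3, 7 and 9 days and -0.54 in cured choroid plexus macrophages, whose interferon-gamma median was 0.94.

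Cells thinned to 2000 UMIs gave identity medians of -1.39 in infected microglia, -4.02 in recruited cells, -2.49 in infected and -0.33 in cured choroid plexus macrophages and -1.01, -0.66 and -0.55 at 3, 7 and 9 days, where the interferon-gamma medians were 3.26, 1.26 and 1.45. Thinning turned the alternative activation list of MF8 to 1.20, over members chosen anew in the thinned counts. Subtraction of free RNA gave -1.08 at 3 days and -0.40 in subdural macrophages. With every marker in the estimate it gave -1.49 in infected microglia, -3.77 in infected choroid plexus macrophages, -1.09 at 3 days and -0.43 in subdural macrophages. It also turned H2-Aa in 8-week against naive microglia to -4.48, by removal of nearly all 8-week counts of that gene. Members with at least 1 UMI gave -3.94 for border-associated genes in infected choroid plexus macrophages and 1.53 for interferon-gamma genes at 7 days.

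All annotated cells, whatever their class, gave identity medians of -1.61 in infected microglia, -3.78 in recruited cells, -3.35 in the infected choroid plexus, -1.13 in the cured choroid plexus and -0.046 in the subdural meninges. Their interferon-gamma medians were 1.77, 1.42 and -0.032 in these 3 tissues, and the type I interferon median set beside epi BAM turned to -0.26. All macrophage classes gave interferon-gamma medians of 1.75 in the infected and 1.34 in the cured choroid plexus, and -0.89 for border-associated genes in the latter. The first pools gave -3.77 for homeostatic genes in recruited cells, 1.75 for interferon-gamma genes in the infected and -0.91 for border-associated genes in the cured choroid plexus.

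Cells that passed the marker rule gave identity medians of -4.10 in recruited cells, -3.78 in infected and -0.55 in cured choroid plexus macrophages, -0.18 in subdural macrophages and -0.86, -0.62 and -0.69 at 3, 7 and 9 days. Their interferon-gamma medians were 2.92, 1.36 and 0.52 at these days and -0.29 in subdural macrophages. They also turned the cell cycle list to 0.092 in MF8 and -0.037 at 3 days and the cytokine list to -0.023 at 9 days.

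Cells with Xist alone gave interferon-gamma medians of 1.012 in cured choroid plexus and -0.0058 in subdural macrophages, and border-associated medians of -0.38 and -0.55. Clusters weighted to their control shares gave -0.035 and -0.19 in subdural macrophages. Cells with Y-linked RNA alone gave interferon-gamma medians of 2.07 in infected and 0.96 in cured choroid plexus and 0.43 in subdural macrophages, with -2.80, -1.28 and -0.24 for border-associated genes. They also turned Cxcl2 of subdural macrophages to 1.32, from very few cured UMIs.

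The own assignment by markers put 3.33%, 20.6%, 32.5% and 75.2% of cells in microglia at 3, 7 and 9 days and 8 weeks, and 14.2% of cured choroid plexus cells in cDC2, which made up 19.98% of the sum of macrophages, monocytes and cDC2 cells. Apart from the scaling, the cause was not tested for any of these values. Free RNA could not be subtracted from the CD45hi sort, whose matrix holds no empty droplets. The sex split gave no value for cells with Xist alone against the naive choroid plexus, which held 0 such cells. A minimum of 1000 UMIs removed no cell. Few cells limit the values from the marker rule, which 23, 16 and 39 microglia passed at 3, 7 and 9 days.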

Other observations

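All values here were chosen after the data were seen, and none was tested. Lymphoid and dendritic cells of the choroid plexus were annotated beside the macrophages. Natural killer cells made up 14.2% (13.1 to 15.3) of the naive and 1.03% (0.806 to 1.30) of the infected library, T cells 7.897% and 3.38% and dendritic cells 5.13% and 2.68%. The naive library was gated on CD45 alone and the infected one on CD45 and CD11b, so these shares cannot be read as an effect of infection. Monocytes stood at 1.26% and 18.6%. The CD45hi sort of infected brains held 66.7% macrophages, 11.97% classical and 12.8% non-classical monocytes, 2.95% T cells, 2.17% dendritic cells and 1.34% microglia. In the infected microglia sort 5.32% of cells were proliferating and 2.49% were T cells.

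The YFP label was also unevenly spread over smaller classes. In the infected choroid plexus it was found in 15.7% (10.5 to 22.1) of the 166 cells of MF7 and 25.6% (18.1 to 34.4) of the 121 proliferating cells, against 2.91% of the 1065 cells of MF3, and thinning to 2000 UMIs gave 12.7%, 19.8% and 1.69%. Over all pooled cells of MF 1 to 4, alternative activation genes were lower in cured than control mice in 5 of 5 at -1.08 (-1.17 to -0.54), or -0.48 with clusters weighted to their control shares, lipid handling genes were higher in 10 of 10 at 0.26 (0.20 to 0.31), and lysosome genes stood at 0.14 (0.10 to 0.19). In recruited cells of the infected brain scavenger and Fc receptor genes stood at 0.37 (0.31 to 0.43), or 0.76 relative to the median gene against microglia and lipid handling genes at 0.38 (0.30 to 0.49), or 0.77 relative to the median gene.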
